A study of Homo sapiens with 6 samples.

How the data were processed

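Transcript levels were measured by RNA sequencing in 6 libraries from 3 established human colorectal cancer cell lines, HCT116, HT29 and SW480. Each line gave 1 library with a non-targeting hairpin RNA and 1 with a hairpin against BZW2. Groups were taken from the treatment label of each sample, and the cell line label gave the replicate number.

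Per the submitters' processing notes, the tools named were bcl2fastq 2.17, STAR 2.5.2b and DESeq, with the GRCh38 genome build. The gene counter, the annotation release and the strandedness of the libraries are not given in the sources used here, so overlapping genes, antisense genes and near-identical gene copies such as the histone and tubulin genes carry an uncertain split of reads. The deposited table held a normalised signal per gene and library, made by the authors by dividing gene read counts by a size factor. The values showed that the size factors were set separately for the 2 libraries of each line, since the factors of a line multiplied to 1. Levels were therefore compared within a line. Dividing each column by its smallest step returned whole reads for 100% of values within 0.1 read. In the SW480 control library the smallest listed value stood for 2 reads, so its step was set at that value divided by 2. In each line the listed genes had at least 21 reads summed over both libraries, and genes at or below 20 reads were blank.

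The deposited table had 266314 rows for 13040 gene identifiers. Of these, 19 identifiers were repeated, 12 of them over 20592 rows each, in rows that combined values of different genes, and they were left out. The remaining 13021 identifiers comprised 10875 listed in all 3 lines, 1228 listed in 2 lines, 467 listed in 1 line and 451 listed in none. Gene symbols matched 13003 identifiers through a gene name table, and GENCODE 29 on GRCh38 matched 13018 and gave coordinates, biotype, transcript length and GC content. Length and GC content were those of the longest transcript of each gene.

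Depth over listed genes ranged from 2187373 reads in the HCT116 knockdown library to 9317444 in the HT29 control library. Counting intervals are exact Clopper-Pearson intervals at 95% for the ratio of reads of 2 libraries. They cover counting error only. A gene with 0 reads in a library was given a floor of 3 reads in that library for a bound on its fold.

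The design fixed before the data were examined assumed either raw counts or normalised values. Because the table held normalised values, the main test across lines was limma 3.58.1 in R 4.3.3 on log2 of the value plus a pseudocount of 1, with cell line and treatment as terms and an intensity trend in the empirical Bayes step. Genes needed a value of at least 1 in at least 3 libraries, which removed 0 of the 10875 genes. Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. A fold change on the log2 scale of value plus pseudocount understates the change of low genes. Cell lines served as the replicates, and nothing in the labels speaks of repeat cultures of a line. A gene's limma p therefore rests on the spread of its treatment difference among these 3 lines, moderated by other genes. The design left 2 residual degrees of freedom against 7.26 prior ones, so most weight lay on spread pooled over genes. The pairing of libraries came from the shared cell line. After group means were removed, the 2 libraries of a line correlated at 0.28 in HCT116, 0.75 in HT29 and 0.45 in SW480, above the correlation of the line's knockdown library with the control of any other line.

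Within a line no test was possible with 1 library per treatment. The log2 ratio of TMM-scaled CPM from the recovered reads was taken with edgeR 4.0.16 and a prior count of 2, and genes with at least a 2-fold ratio and CPM of at least 5 in the higher library were counted. Gene lists were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. With an estimated correlation camera uses the 2 residual degrees of freedom of the design, and fewer with a line left out. A call lost there can follow from that alone, so it does not show that correlation between genes undid it. At the preset correlation camera takes its spread from between genes, so its p does not measure spread among lines. A list of members was also tested gene by gene with p adjusted over the list alone. Within a line the median log2 ratio of a list was placed among 10000 random lists of the same size matched on expression. Random lists were drawn gene by gene and lack the correlation among members of a real list. Their percentiles therefore describe the libraries and do not measure spread among lines. Lists were fixed before the data were examined, and some share members. They covered DNA replication, mitosis, replication-dependent histones, ATF4 targets, the unfolded protein response, hypoxia and glycolysis, interferon response, mitochondrially encoded mRNAs, nuclear respiratory chain subunits, ribosome biogenesis, ribosomal proteins, sterol and lipid synthesis, p53 targets, epithelial, mesenchymal, ERK output, immediate early and heat shock, Wnt targets, apoptosis, translation initiation and NF-kappaB genes. Lists of colon differentiation genes and of endothelial, fibroblast, leukocyte and packaging cell markers had 2, 1, 0, 0 and 0 members listed in all 3 lines, under the minimum of 5, and were not tested.

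Named genes followed a rule fixed before the data were examined. BZW2 and BZW1 were always reported. Because fewer than 10 genes passed in each direction, the 10 genes of smallest p in each direction with the same sign in all lines and a log2 fold change of at least 1 in size were taken. Within a line the 6 largest and 6 smallest ratios were taken, and per list the 4 members with the largest fold change. The text prints some of these, and 1 gene is not reported here.

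Alternatives fixed beforehand were DESeq2 1.42.0 and limma-voom on recovered reads, other scalings, pseudocounts, filters and size rules, a model without the line term, and each line left out. A fit with a line left out rests on 2 lines, with 1 library per line and treatment. Alternatives chosen after seeing the data were edgeR's quasi-likelihood test on recovered reads, TMM over all libraries, genes listed in at least 2 lines, library weights, lists in HT29 and SW480 alone with an estimated correlation, and correction of each line's log2 ratios for transcript GC content and length with natural splines. GC content and length were known for 10873 of the 10875 genes. The tests were checked on simulated counts for the 10875 genes of the comparison across lines. At a dispersion of 0.05, limma called 46% of genes changed 2-fold and 100% of genes changed 4-fold, with 6 false calls. At a dispersion of 0.15 it called 14% and 68%, with 7 false calls. Each simulated gene changed equally in every line at the same dispersion. The real ratios spread unequally, with an SD of 1.59 in HCT116 against 0.66 in HT29 and 0.67 in SW480. These shares are therefore not the power of the test on these libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.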

Results

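The series compared colorectal cancer cells in which BZW2 was depleted by a stable lentiviral short hairpin RNA (shRNA) with cells carrying a non-targeting shRNA, to find the genes and pathways that differ. HCT116, HT29 and SW480 are established colorectal cancer lines, and transduced cells had been selected with puromycin at 1 µg/ml. There was 1 library per line and treatment, so each group held 3 libraries, 1 from each line. Reads over listed genes came to 5640626 in the HCT116 control and 2187373 in the HCT116 knockdown library, to 9317444 and 8968603 in HT29, and to 5078001 and 6105605 in SW480. In the HCT116 knockdown library 129 listed genes had 0 reads, against 0 in the HT29 and 2 in the SW480 knockdown library. A total of 10875 genes were listed in all 3 lines.

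BZW2, a relative of the translation initiation factor eIF5, was far lower in the knockdown library of every line. The gene (ENSG00000136261) spans positions 16646131 to 16706523 of chromosome 7 (GRCh38). The part of the transcript that the hairpin targets was not analysed here. In HCT116 the knockdown library held 17.4% of the control level (95% counting interval 11.5 to 25.3%, 29 against 530 reads). In HT29 it held 8.66% (7.20 to 10.3%, 133 against 1590 reads), and in SW480 13.3% (10.3 to 16.9%, 77 against 456 reads). Across lines the log2 fold change was −2.92 ± 0.40 (SE, n = 3 lines), with a limma adjusted p = 0.155 over all genes and 0.00154 when adjusted over the list alone of translation initiation factors. It passed over all genes without HCT116 (−3.16, limma adjusted p = 3.09e-04) and without SW480 (−2.96, limma adjusted p = 0.00477). Its paralog BZW1 (ENSG00000082153) showed no shared direction, at 55.8% of control in HCT116, 134% in HT29 and 89.0% in SW480, with a log2 fold change of −0.14 ± 0.39. The sign of that BZW1 estimate turned without HCT116 (0.17).

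**Figure D1:**
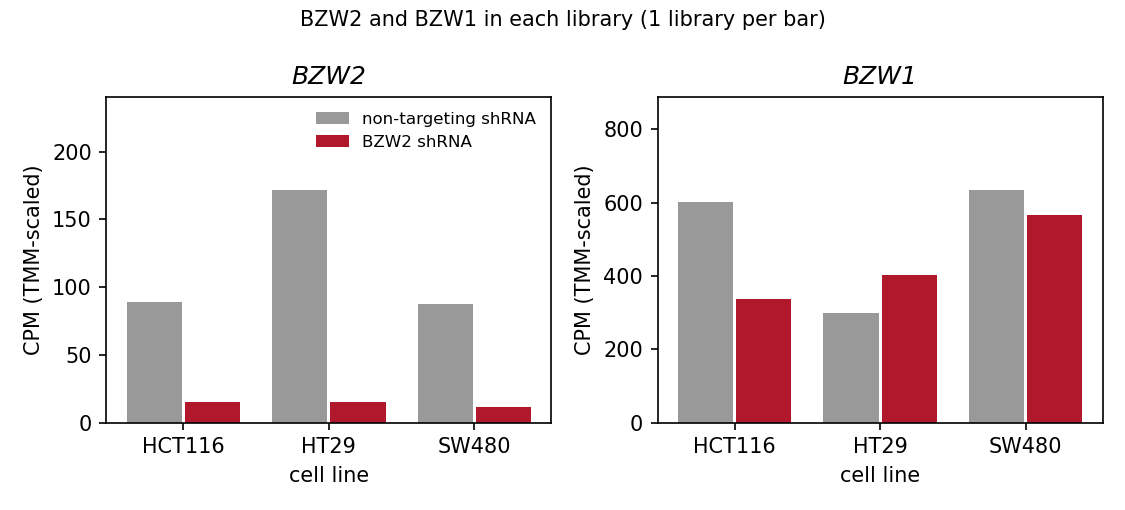
TMM-scaled CPM of BZW2 (left) and BZW1 (right) in each of the 6 libraries, 1 bar per library, grey for non-targeting and red for BZW2 shRNA. BZW2 lay between 11.6 and 15.5 CPM in the knockdown libraries and between 87.3 and 172 CPM in the controls, whereas BZW1 was lower with BZW2 shRNA in HCT116 and SW480 and higher in HT29.

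The comparison across the 3 lines asked which genes differed with BZW2 shRNA whatever the line. The 10 genes of smallest p that were lower in every line included BZW2 itself, 1 ATF4 target, DDIT3, and 2 genes of the hypoxia list, NDRG1 and P4HA1. DDIT3, which encodes the stress transcription factor CHOP, had a log2 fold change of −3.74 ± 0.46 (SE), with 33 against 2021 reads in HCT116, 409 against 2410 in HT29 and 108 against 2099 in SW480. NDRG1, a hypoxia-induced gene, stood at −3.31 ± 0.45 and P4HA1, a collagen prolyl hydroxylase subunit, at −2.37 ± 0.39. The calcium channel gene TRPV6 stood at −3.94 ± 0.63 and the interferon-induced IFITM1 at −2.99 ± 0.56, both with 0 reads in the HCT116 knockdown library, so that these fitted values depend on the pseudocount. PKIB, an inhibitor of protein kinase A, was at −2.65 ± 0.48, and NIBAN1, a stress-responsive gene, at −2.30 ± 0.42.

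The genes of smallest p that were higher in every line included genes of mitosis and DNA replication. The mitotic cyclin gene CCNB1 had a log2 fold change of 2.32 ± 0.41 and the mitotic kinesin gene KIF20A 2.31 ± 0.39. ZWINT, a kinetochore gene, was at 2.16 ± 0.37, CCNA2, the S and G2 phase cyclin, at 2.11 ± 0.39, and the mitotic kinase gene AURKA at 2.10 ± 0.38. ORC1, part of the origin recognition complex, was at 2.07 ± 0.43, the flap endonuclease gene FEN1 at 1.84 ± 0.37 and BIRC5, which encodes survivin, at 1.71 ± 0.35. The histone gene H3C12 was at 3.58 ± 0.73, with log2 ratios of 6.32 in HCT116, 1.83 in HT29 and 2.60 in SW480, and the estimate was 2.21 without HCT116.

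No single gene passed the threshold over all genes in the limma test, in which the smallest adjusted p was 0.155. At an unadjusted p under 0.05 there were 766 lower and 717 higher genes, where 543.75 in all would be reached by chance. The same sign in all 3 lines was seen for 4724 genes (43.4%, against 25% if lines were independent). The ratios followed transcript length in all lines and GC content in HCT116 and HT29, which can raise this share. It was not recomputed after correction for these trends. The count depended on the tool and the lines: DESeq2 on recovered reads called 134 lower and 110 higher genes, whereas edgeR and limma-voom called 0 (edgeR: 1287 genes at an unadjusted p under 0.05). Without HCT116, whose log2 ratios spread most widely, limma called 151 lower and 187 higher genes, of which 133 (88.1%) and 167 (89.3%) had the same sign in HCT116. Without HT29 it called 27 and 30, and without SW480 93 and 44. Fits with a line left out have fewer residual degrees of freedom than the 2 of the full design. They rest still more on spread pooled over genes, so their larger counts are not stronger evidence.

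**Figure D2:**
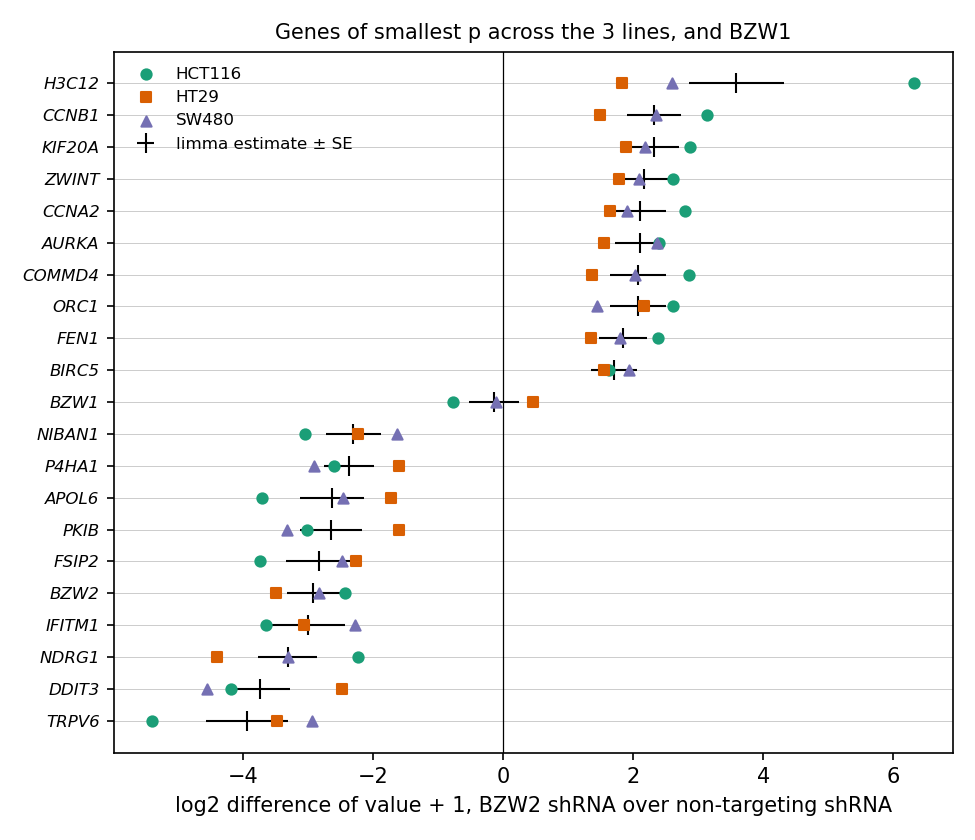
Log2 difference of value plus 1 between BZW2 shRNA and non-targeting shRNA for the genes of smallest p in each direction and for BZW1, with 1 coloured point per line and the limma estimate ± SE in black. Genes other than BZW1 were chosen to have the same sign in all 3 lines, so their agreement between lines follows from that choice. H3C12 in HCT116 (6.32) lay farthest from 0.

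Genes of DNA replication and of mitosis rose as groups. Among 25 replication genes tested, all had a positive fold change, 22 were higher in each of the 3 lines and 20 rose when adjusted over the list alone, while 0 passed over all genes. The minichromosome maintenance genes MCM5 and MCM2, parts of the replicative helicase, had log2 fold changes of 2.26 ± 0.52 and 1.88 ± 0.46 (1.44 and 1.22 without HCT116), and CDC45, its cofactor, 1.86 ± 0.41. Among 28 mitosis genes, 26 had a positive fold change and 18 rose when adjusted over the list alone, among them CDC20, an activator of the anaphase-promoting complex (2.56 ± 0.53), and PLK1, a mitotic kinase (2.37 ± 0.72). HCT116 carried much of both estimates, which were 1.71 and 1.11 without it, the latter not past the threshold over all genes. The median log2 ratios of the replication list were 1.67 in HCT116, 1.14 in HT29 and 1.26 in SW480, and those of the mitosis list 1.35, 1.13 and 1.37, each at or above the 99.99th percentile of random lists. Camera gave an adjusted p of 4.6e-14 for both lists, and each call was lost at adjusted p = 0.318 with an estimated correlation. The first value draws on spread between genes and the second on 2 residual degrees of freedom, as for every list below. Without HCT116, 16 replication and 19 mitosis genes passed over all genes.

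ATF4 target genes, which belong to the integrated stress response, fell as a group. Of 24 tested, 22 had a negative fold change, 17 were lower in each of the 3 lines and 9 fell when adjusted over the list alone. After DDIT3, the largest were SLC7A11, the cystine transporter gene (−2.37 ± 0.60), and CHAC1, a glutathione-degrading enzyme gene (−2.16 ± 0.51), both of which fell on that adjustment, and ALDH1L2, a mitochondrial folate enzyme gene (−2.15 ± 0.80), which did not. Without HCT116 these 3 stood at −1.37, −2.04 and −0.98. The list medians were −1.10 in HCT116, −0.91 in HT29 and −1.37 in SW480. The camera adjusted p was 1.04e-09, and the call was lost at adjusted p = 0.318 with an estimated correlation. Without HCT116, 10 members passed over all genes.

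Genes of the unfolded protein response of the endoplasmic reticulum also fell as a group. Of 22 tested, 20 had a negative fold change, 16 were lower in each of the 3 lines and 9 fell when adjusted over the list alone. HSPA5, the main chaperone of the endoplasmic reticulum, stood at −2.03 ± 0.44, the chaperone cofactor gene DNAJB9 at −2.45 ± 0.59 (−1.48 without HCT116), and HERPUD1 and SEL1L, both of protein degradation at the endoplasmic reticulum, at −2.34 ± 0.45 and −2.18 ± 0.42. Medians were −1.52 in HCT116, −0.40 in HT29 and −1.11 in SW480. The camera adjusted p was 6.72e-09, and the call was lost at adjusted p = 0.513 with an estimated correlation.

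Hypoxia and glycolysis genes fell as a group across lines, with HCT116 apart from the other 2 lines. Of 28 tested, 20 had a negative fold change, 11 were lower in each line and 8 fell when adjusted over the list alone. Besides NDRG1 and P4HA1, these included BNIP3L, a mitophagy receptor gene (−2.27 ± 0.49), and PDK1, a pyruvate dehydrogenase kinase gene (−1.74 ± 0.37). The median was −0.78 in HT29 and −1.58 in SW480, each below all random lists, and 0.27 in HCT116, within the range of random lists. That HCT116 median hides a split, with 10 members at least 2-fold higher and 7 at least 2-fold lower. The camera adjusted p was 2.03e-04, and the call was lost at adjusted p = 0.716 with an estimated correlation. It was also lost without SW480 (camera adjusted p = 0.157), while without HCT116 12 members passed over all genes.

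Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, rose in all 9 members tested, each when adjusted over the list alone. These were the 9 of the list's 26 symbols that were listed in all 3 lines. The estimated correlation between them was 0.995, so they are far from 9 separate observations. Without HCT116, 3 of them passed over all genes. H2BC4 had a log2 fold change of 3.19 ± 0.77 and H4C3 of 2.70 ± 0.82, against 1.70 and 1.14 without HCT116. The median log2 ratio was 4.97 in HCT116, 1.12 in HT29 and 0.74 in SW480. In the same HCT116 pair, 63 of 63 genes for small nuclear, nucleolar and Cajal body RNAs were higher in the knockdown library, with a median of 3.16, against 0.09 in HT29 and −0.62 in SW480. The camera adjusted p for histones was 1.44e-07, and the call was lost at adjusted p = 0.590 with an estimated correlation.

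Mitochondrially encoded mRNAs were lower as a list in camera, and nuclear genes for respiratory chain subunits higher, in neither case with a gene past the threshold. All 13 mitochondrial mRNAs had a negative fold change, and 0 passed when adjusted over the list alone; MT-CO3 was at −1.28 ± 0.47 (−0.63 without HCT116) and MT-ND4 at −1.20 ± 0.38. Their medians were −1.73 in HCT116, −0.92 in HT29 and −0.29 in SW480, the last within the central 95% of random lists (camera adjusted p = 1.33e-05; adjusted p = 0.590 with an estimated correlation). Of 31 nuclear subunit genes, 29 had a positive fold change and 0 passed when adjusted over the list alone, with CYC1, cytochrome c1, at 1.17 ± 0.45 (0.56 without HCT116) and medians of 0.43 in HCT116, at the 77.05th percentile of random lists and so within their range, 0.49 in HT29 and 0.41 in SW480 (camera adjusted p = 2.03e-04; adjusted p = 0.318 with an estimated correlation).

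Type I interferon response genes fell as a list by camera (adjusted p = 0.00147; adjusted p = 0.724 with an estimated correlation), but the lines went opposite ways. The median log2 ratio was −1.71 in HCT116, −2.36 in HT29 and 0.96 in SW480, and 1 of the 18 members was lower in all 3 lines. IFIT1, an interferon-induced RNA-binding protein gene, had log2 ratios of −2.68 in HCT116, −3.65 in HT29 and 2.55 in SW480. No member passed when adjusted over the list alone, and the call was lost without HT29 (camera adjusted p = 0.746). Ribosome biogenesis and MYC target genes passed as a higher list (21 of 26 with a positive fold change, camera adjusted p = 0.00294; adjusted p = 0.716 with an estimated correlation), with medians of 0.96 in HCT116, −0.04 in HT29, within the range of random lists, and 0.38 in SW480. The pyrimidine synthesis gene CAD was at 1.45 ± 0.56 and at 0.55 without HCT116, without which the list's call was lost (camera adjusted p = 0.115). Cytosolic ribosomal protein genes passed as a lower list (43 of 52 with a negative fold change, median −0.25, camera adjusted p = 0.0347; adjusted p = 0.863 with an estimated correlation), a call lost without HCT116 (camera adjusted p = 0.424) and without SW480 (0.647). Their medians were −0.71 in HCT116 and −0.54 in SW480 but 0.31 in HT29, and 0 of the 52 were lower in all lines. In neither list did a member pass when adjusted over the list alone.

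The other 10 lists did not pass in camera. Adjusted p was 0.0796 for sterol and lipid synthesis, 0.132 for p53 targets and for epithelial genes, 0.134 for ERK output, 0.491 for immediate early and heat shock genes, 0.507 for Wnt targets, 0.617 for apoptosis genes, 0.690 for mesenchymal genes, 0.922 for translation initiation factors and 1.00 for NF-kappaB genes. Some single members passed when adjusted over the list alone. EGR1, a growth-factor-induced transcription factor gene, fell (−2.13 ± 0.42), as did the immediate early genes ATF3 (−1.90 ± 0.40) and KLF4 (−1.47 ± 0.42), the EGF receptor ligand gene AREG (−1.64 ± 0.43) and the fibronectin gene FN1 (−1.87 ± 0.49), and the apoptosis list had 1 that rose, BIRC5. Among initiation factors BZW2 was the 1 member past that threshold, and the list median was −0.03. Leaving out HCT116 brought the epithelial list (adjusted p = 8.3e-05), the ERK list (0.00697) and the immediate early list (2.6e-05) below the threshold as lower, with 7 immediate early genes past it over all genes, and the p53 list (0.0336) as higher. These calls were lost at adjusted p = 0.596, 0.542, 0.542 and 0.829 with an estimated correlation. Leaving out HT29 brought sterol and lipid synthesis genes below the threshold as higher (0.0145 at the preset correlation), where over all lines adjusted p = 0.782 with an estimated correlation. Camera pointed lower for the immediate early and mesenchymal lists although their median fold changes were 0.11 and 0.17, and higher for the NF-kappaB list although its mean was −0.13.

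**Figure D3:**
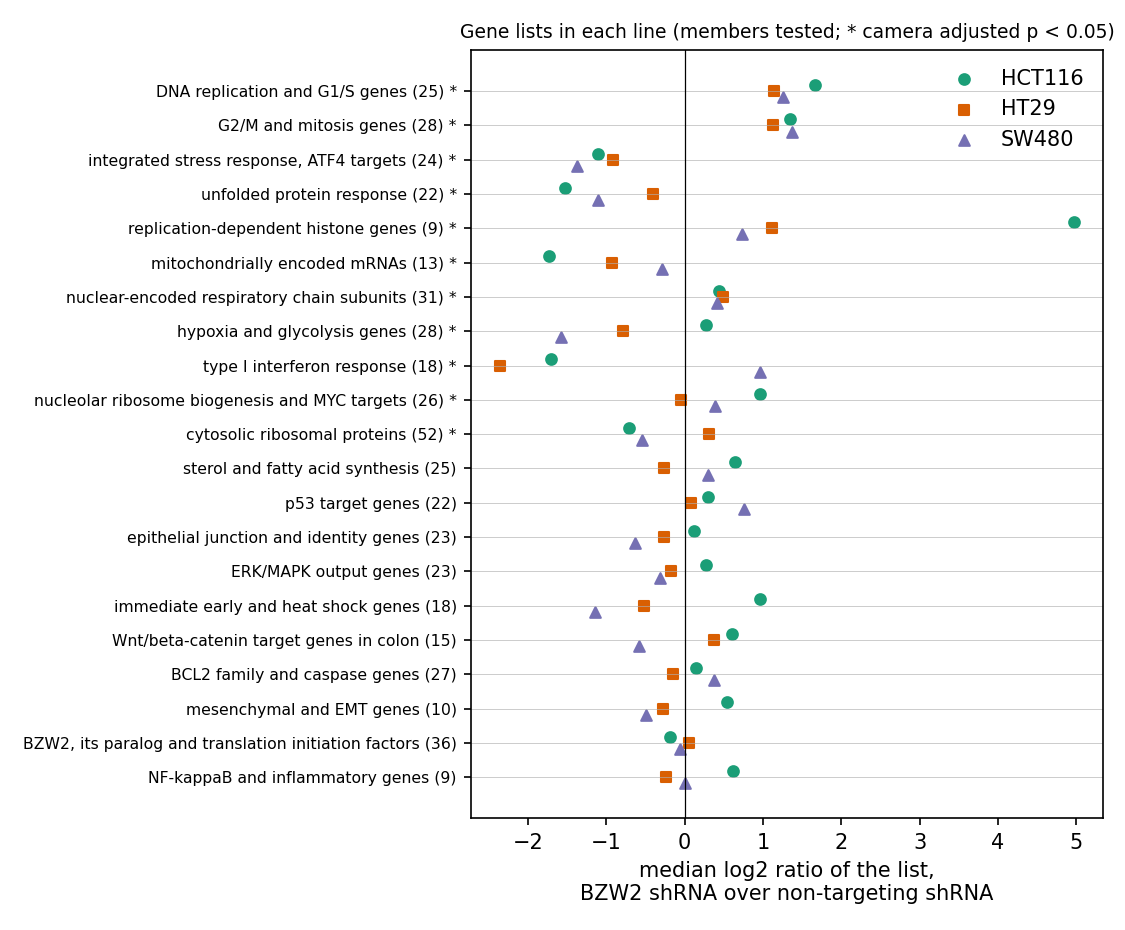
Median log2 ratio of each tested gene list in HCT116 (circles), HT29 (squares) and SW480 (triangles), with the number of members in parentheses and an asterisk for a camera adjusted p under the threshold at the preset correlation. Replication and mitosis medians lay between 1.13 and 1.67 in all lines, ATF4 target medians between −1.37 and −0.91, and the interferon median was 0.96 in SW480 against −1.71 and −2.36 in the other lines.

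Within HCT116 the knockdown library differed from its control in far more genes than in the other lines. At least 2-fold differences were seen in 3027 genes higher and 3389 lower of 11415 with enough reads, and with scaling by library size alone the split was 2277 and 4148, since the median of all genes then lay at −0.36. The SD of the log2 ratios was 1.63, and the ratios correlated across genes with transcript GC content (Spearman 0.685; genes are not independent replicates). The largest ratios upward were histone genes: H3C12 was 76.7-fold higher (95% counting interval 69.7 to 84.7), H2BC13 78.7-fold (59.1 to 107) and H2AC7 70.5-fold (59.6 to 84.1). Several genes with over 100 control reads had 0 reads after knockdown. ATP8A1, a phospholipid flippase gene, was at least 19.7-fold lower (188 control reads), SPX, which encodes the peptide spexin, at least 16.6-fold lower (158 reads), and DPP4, which encodes a dipeptidyl peptidase of the cell surface, at least 15.2-fold lower (145 reads), from a floor of 3 reads in that library. The wider 95% counting intervals reached up to 6.30%, 7.51% and 8.20% of control, so they allow somewhat smaller folds.

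Within HT29, the lowest genes relative to control included LAMP3, NDRG1 and interferon-induced genes. Of 10104 genes with enough reads, 366 were at least 2-fold higher and 622 lower. NDRG1 was at 4.63% of control (4.12 to 5.18%), and the interferon-induced genes SAMD9, IFIT1, MX1 and DDX60 at 7.21%, 7.75%, 8.23% and 8.47%. LAMP3, a lysosomal membrane protein gene, was at 3.24% (1.17 to 7.17%, 6 against 192 reads). The tubulin gene TUBA1A, which has near-identical copies, was 10.9-fold higher (7.09 to 17.5), ORC1 4.43-fold (3.39 to 5.86) and HMGB3, a chromatin protein gene, 4.23-fold (3.81 to 4.70).

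Within SW480, DDIT3 and the glucose transporter gene SLC2A3 were among the lowest. Of 11032 genes with enough reads, 516 were at least 2-fold higher and 851 lower. DDIT3 was at 4.05% of control (3.30 to 4.91%), SLC2A3 at 5.05% (4.26 to 5.95%) and ENTPD8, an ectonucleotidase gene, at 2.03% (0.41 to 6.10%, 3 against 116 reads). The extracellular matrix gene TNC had 28 control reads and 0 after knockdown, at least 11.9-fold lower. SUSD2, a membrane protein gene, was 11.7-fold higher (5.99 to 26.2, 134 against 9 reads), and AQP3, a water and glycerol channel gene, 6.95-fold (3.82 to 13.9). Differences within a line have no replicate check.

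**Figure D4:**
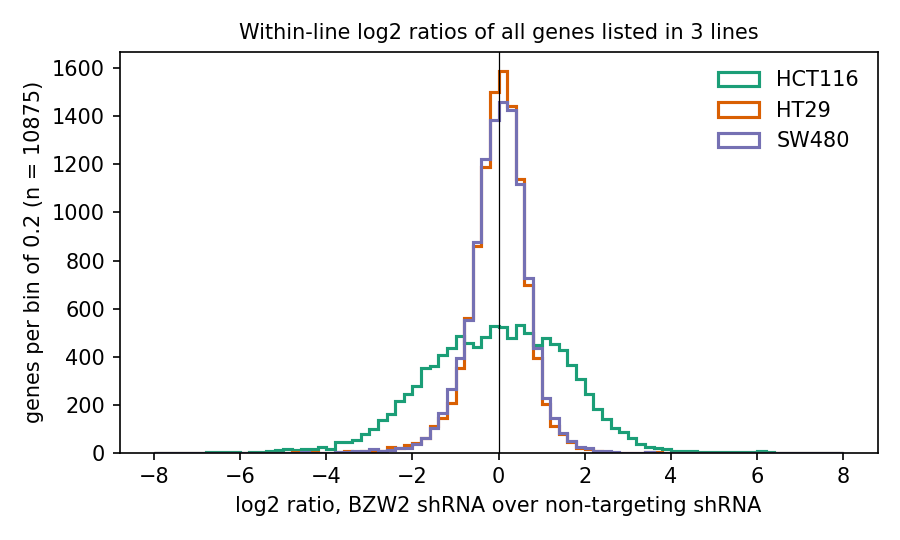
Number of genes per bin of log2 ratio (BZW2 shRNA over non-targeting shRNA, bins of 0.2) for the 10875 genes listed in all lines, 1 outline per line. HCT116 was spread far more widely than HT29 and SW480, with an SD of 1.59 against 0.66 and 0.67 on this scale.

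Part of the difference was shared between the lines, which have no library in common. Of 9644 genes with enough reads in all lines, 106 were at least 2-fold higher and 86 at least 2-fold lower in every line, where 3.91 and 9.77 would be reached if lines were independent. Of the 106 higher genes, 27 were on the replication or mitosis lists and 3 on the histone list, with 11 further histone cluster genes outside the list, and of the 86 lower genes 14 were on the ATF4, unfolded protein or hypoxia lists. Across genes, log2 ratios correlated between HCT116 and HT29 (Pearson 0.47, Spearman 0.46), HT29 and SW480 (0.41 and 0.40) and HCT116 and SW480 (0.30 and 0.27). The ratios also followed transcript GC content in HCT116 and HT29 (Spearman 0.685 and 0.318) but hardly in SW480 (−0.050). After correction for GC content and length the Pearson correlations were 0.35, 0.44 and 0.45 in the same order, and 79 higher and 91 lower genes were shared. Genes are not independent replicates, so these values describe the libraries. At CPM of at least 20 the shared lower genes numbered 53.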

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

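The lists below were picked out after their values were seen, because their median lay beyond the central 95% of random lists in opposite directions in different lines. With 1 library per line and treatment the difference between lines was not tested. The interferon list had a median log2 ratio of −1.71 in HCT116, −2.36 in HT29 and 0.96 in SW480. The ribosomal protein list had a median of −0.71 in HCT116, 0.31 in HT29 and −0.54 in SW480. The Wnt target list had a median of 0.37 in HT29 and −0.58 in SW480, with 0.61 in HCT116 inside the central range.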

How the results depend on the processing

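The added alternatives (edgeR, TMM over all libraries, genes in at least 2 lines, library weights, GC and length correction of genes, lists and shared genes, lists in HT29 and SW480 with an estimated correlation) were chosen after seeing the data. The count of genes across lines was 0 in limma as reported and moved under 3 kinds of change whose cause was not tested: DESeq2 called 134 lower and 110 higher, leaving out 1 line gave 27 to 151 lower and 30 to 187 higher, and library weights, which set HT29 at 5.08 and HCT116 at 0.18, gave 1416 and 1399. The other settings called 0, including the model without the line as replicate block, which called 0 genes, 5 lists higher and 5 lower (191 genes at an unadjusted p under 0.05), and changed no call other than that of ribosomal proteins, lost. The smallest adjusted p of limma-voom was 0.0692 and of the GC and length correction 0.0547. BZW2 passed with DESeq2 (−2.99, adjusted p = 9.4e-08), with library weights (−3.35), and without HCT116 or SW480, and ranged from −3.16 to −2.64 with lines left out in turn. BZW1 changed sign with lines left out in turn (−0.44 to 0.17), with library weights (0.32) and with the GC and length correction (0.49).

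All 11 lists called by camera (5 higher, 6 lower) were lost with an estimated correlation (0 and 0, also without HCT116) and with fry (0 and 0). Loss with an estimated correlation can follow from its 2 residual degrees of freedom alone. The nuclear respiratory chain list was lost there although its estimated correlation, −0.017, was below the preset 0.01. The 11 lists kept their call with other scalings, with the stricter filter and with the GC and length correction, which added the epithelial, ERK and immediate early lists (14 in all). Library weights added the same 3, lost ribosome biogenesis, and turned the ribosomal protein list, at a camera p of 0.0561 (adjusted p = 0.0906, limma). Within lines, a 1.5-fold rule gave 1338 higher and 1597 lower genes in HT29 and 1601 and 2015 in SW480, and 364 shared higher and 364 shared lower genes, since it admits smaller ratios. The GC and length correction moved the correlation of HCT116 with SW480 from 0.30 to 0.45, and that of HCT116 with HT29 from 0.47 to 0.35. HCT116 and HT29 carry a GC trend that SW480 hardly has, and all lines carry a length trend. Both were corrected together, so their parts in these moves were not separated. With CPM of at least 20, lower genes numbered 444 in SW480 and 53 in all lines, since fewer genes enter. Library size alone moved the median log2 fold change by −0.13. The depth of 2187373 reads in the HCT116 knockdown library limits genes of low level there.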

Other observations

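The genes in this paragraph were singled out after their values were seen. Of the 106 genes at least 2-fold higher in every line, 75 were on none of the fixed lists, 11 of them histone cluster genes. PIF1, a DNA helicase gene, had log2 ratios of 3.51 in HCT116, 1.80 in HT29 and 1.92 in SW480, and ASF1B, a histone chaperone gene, 2.21, 1.60 and 1.79. LMNB1, a nuclear lamin gene, had 1.41, 1.65 and 1.54, and MYBL2, a cell cycle transcription factor gene, 3.12, 1.73 and 1.37. Of the 86 genes at least 2-fold lower in every line, 70 were on no list. They included the autophagy genes MAP1LC3B (−2.82, −1.18 and −1.73) and WIPI1 (−2.13, −1.13 and −1.30), the polyamine acetyltransferase gene SAT1 (−5.70, −1.30 and −2.68), and MXD1, a MAX partner that opposes MYC (−2.04, −1.13 and −1.95). Among p53 targets, TP53I3 had log2 fold changes of 1.52 ± 0.45, FDXR 1.16 ± 0.37 and BAX 1.07 ± 0.38, positive in all 3 lines, 3 of the 8 among 22 targets that were so, while 3 targets were negative in all 3 lines. None of the 22 passed when adjusted over the list alone.

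In the patterns that follow, the tests of depth and of GC content on the HCT116 spread were set before their results were seen, and the other tests were chosen after. The log2 ratios of HCT116 had an SD of 1.59, against 0.66 in HT29 and 0.67 in SW480. Shallow sequencing is argued against, since among the 2721 genes with the most reads the HCT116 SD was still 2.40 times the larger of the other 2. A trend with GC content and length explained 46.0% of the HCT116 variance. After its removal the SD was still 1.77 times the larger of the other 2, so the trend as fitted was not the whole cause. The fit used the longest transcript of each gene, so a trend with the transcripts actually expressed may not be fully removed. A stronger knockdown in HCT116 than in HT29 was not seen, since BZW2 kept more of its control level in HCT116 both with TMM (17.4%, 11.5 to 25.3%, against 8.66%, 7.20 to 10.3%) and with library size alone (14.1% against 8.69%). It is not excluded, because with library size alone the intervals overlap (lower bound 9.36% in HCT116, upper bound 10.4% in HT29) and they cover only the counting noise of 1 pair per line. A difference in library preparation of this pair stays open and untested, as does a different response of HCT116 to BZW2 loss.

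Histone mRNAs were far higher in the HCT116 knockdown library than the other replication genes, by 3.30 on the log2 scale with a member SD of 0.69, which argues against a larger share of cells in S phase as the whole cause there. More RNA without a poly(A) tail in that library is a candidate explanation, since genes of small nuclear, nucleolar and Cajal body RNAs had a median of 3.16 in HCT116 against 0.09 and −0.62 in the other lines. In HT29 and SW480 the histone median did not exceed that of replication genes (differences of −0.022 and −0.52), so a larger S phase share may account for it in those lines.

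ATF4 target and unfolded protein response genes were lower, and replication and mitosis genes higher, in each line. A GC and length trend, as fitted on the longest transcript of each gene, is argued against, since each of the 4 lists kept at least 92.6% of its median after correction. The HCT116 pair as the whole cause is also argued against, since the medians went the same way in HT29 and SW480. They were 1.14 and 1.26 for replication, 1.13 and 1.37 for mitosis, −0.91 and −1.37 for ATF4 targets and −0.40 and −1.11 for unfolded protein response genes. Each lay beyond the central 95% of random lists. Those lists lack the correlation among members of a real list, so that position alone decides nothing. Without HCT116 the largest camera adjusted p of the 4 lists was 2.54e-09 at the preset correlation and 0.542 with an estimated one, which also ended the calls over all 3 lines (0.318 to 0.513). Neither p decides here, since the preset one draws on spread between genes and the estimated one on very few residual degrees of freedom. Depletion of BZW2 and an off-target effect of the hairpin cannot be told apart, since the sample titles name the same hairpin in every line. Control cultures that were denser or shorter of nutrients cannot be told apart from either with 1 culture per line and treatment. On culture density and nutrients, the hypoxia list was lower in HT29 and SW480 but at 0.27 in HCT116, within the range of random lists. Its HCT116 members split, with 10 at least 2-fold higher and 7 at least 2-fold lower, so that median decides nothing.

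The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For genes past the limma threshold the real split gave 0 and the highest other split 3167, and with a real count of 0 all 10 splits give as many whatever the data, so the count decides nothing. For lists the real split gave 11 and the highest other 17, and 5 of 10 splits gave as many. The other 4 of these 5 part only HT29 or only SW480, so with the line as a term they test that line's own treatment difference and are no measure of chance. The 2 splits with 3167 genes part HCT116 alone and set its treatment difference against those of the other lines, which points to the wide spread of that pair as a structure of the samples. Among the 4 splits that part every line, the real one gave 1483 genes at an unadjusted p under 0.05 and 11 lists. The other 3 gave 63 to 219 genes and 6 to 9 lists. Each of these reverses the treatment labels within a line, so a difference shared by the lines enters its residual spread and lowers its counts. They are therefore no measure of chance either, and the contrast decides nothing.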
